A study of Acidithiobacillus ferrooxidans ATCC 23270 with 4 samples.

How the data were processed

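Total RNA of Acidithiobacillus ferrooxidans, an acidophilic bacterium that lives by oxidising ferrous iron or reduced sulfur compounds, was extracted with TRIzol and sequenced on Illumina libraries, per the labels' protocols. There were 4 groups, formed from the labels: wild type and a mutant lacking cyc2, each taken into Fe(II) medium from an inoculum kept on Fe(II) or from an inoculum kept on elemental sulfur (switched). Each group had 1 library, so the series held 4 libraries and no replicates, and nothing in the labels gives the time of harvest. The submitters' processing notes name bcl2fastq 2.16 for writing the reads. The aligner, the counting tool, the genome build and the strand setting are not given in the sources used here.

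The deposited files were 2 tables, 1 per growth history, each setting the mutant beside the wild type. The values headed Expression were whole numbers per gene and were taken as read counts not normalized by the authors. The deposited RPKM values were checked: each equals the count divided by the listed gene length and by the column's own total. The authors' log2 ratio is that of mutant RPKM over wild-type RPKM, with an RPKM of 0 set to 0.001. The authors also deposited a P-value and an FDR for each gene from a test whose name is not given in the sources used here; it sets 1 library against 1 library. The authors' tables listed 2513 genes for the Fe(II) pair and 2516 for the switched pair, 2511 of them shared, and a gene missing from a table was set to 0 there. Gene products were taken from the tables, and older locus tags and 2 stable RNA genes from a RefSeq gene table of assembly ASM2148v1, which matched 2428 of the 2518 genes by locus tag. Listed gene lengths differed from that table for 307 genes, and no coordinates are given.

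Depth was 7855783 counts for the Fe(II)-grown wild type, 7626859 for the Fe(II)-grown mutant, 9852960 for the switched wild type and 9485952 for the switched mutant. The tmRNA gene ssrA took 18.8%, 17.5%, 20.4% and 25.3% of these counts, in the same order, and ssrA and the RNase P RNA gene rnpB together took 23.2%, 22.0%, 25.0% and 30.5%. Counting intervals are 95% exact Clopper-Pearson intervals of the mutant's share of both counts, expressed as a log2 ratio. A count of 0 was read as at most 3 counts per library. Intervals and floors cover counting error only, and not the spread between cultures.

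The comparisons, the gene lists, the rule for named genes and most alternatives were set before the data were examined. For each growth history, the ratio of mutant to wild type was taken as log2 after adding 0.5 to each count, with libraries scaled by TMM (edgeR 4.0.16), over genes with a mean of at least 10 counts. With 1 library per group these ratios have no test, and genes at least 2-fold apart were counted as a description of the libraries. TMM scaling and scaling by library total differ here: on library totals every log2 ratio is 0.65 higher in the Fe(II) pair and lower by 0.41 in the switched pair (shift of -0.41). With TMM the median gene stood at 0.04 and -0.01, and with library totals at 0.69 and -0.42. Over all 4 libraries, an additive model of growth history and genotype was fitted with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment at 0.05) on 2473 genes kept by filterByExpr. Its 1 residual degree of freedom is the difference of the mutant effect between the growth histories, so such a difference counts there as error. Its biological coefficient of variation (BCV) was 0.42 and its median prior degrees of freedom 4.21. Standard errors of its log2 fold changes were derived from the F statistics.

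Named genes are cyc2 and the other rus operon genes in every library; per comparison the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 50 counts and a product that is not hypothetical or of unknown function, stable RNA left out; up to 4 members of each list with the largest absolute log2 ratio; and genes past 0.05 in the additive fit with the same direction in both growth histories. Gene lists numbered 28, of which 4 were set by locus tag and 24 by words in the product or symbol. They cover the rus, petI and petII operons, the Hdr-like complex, the bd and bo3 quinol oxidases, assembly of the aa3 oxidase, c-type cytochromes, cytochrome c biogenesis, NADH dehydrogenase, ATP synthase, other sulfur oxidation, sulfate assimilation, carbon fixation, nitrogen fixation, hydrogenase, ribosomal proteins, iron uptake and storage, metal resistance and efflux, chaperones and proteases, oxidative defence, phosphate acquisition, type IV pili and motility, exopolysaccharide and cyclic-di-GMP, mobile elements, conjugation, DNA repair, and stable RNA. The last pattern in fact matched 17 enzymes that modify rRNA or tRNA and is described as that. The ribosomal protein list holds some modifying enzymes, the mobile element list a metal transporter, and the c-type cytochrome list cyc2 itself. A list's median was placed among 10000 random lists of the same size matched on mean expression in 10 bins, for lists of at least 3 measured members. Random lists hold unrelated genes, while several of the fixed lists are operons whose genes can move together. A percentile therefore describes these libraries and is not a measure of rarity.

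Alternatives were scaling by library total, DESeq2 size factors (DESeq2 1.42.0), no minimum count, a minimum of 50, 5 added to each count, the authors' log2 ratio, stable RNA left out, DESeq2 with the same design, limma 3.58.1 on log2(RPKM + 1), and a model without the other factor. All steps ran in R 4.3.3 and Python 3.11.15. The steps were tested on simulated data with the real gene means and library totals, a BCV of 0.4 for every gene and 200 changed genes. This simulation was written after real values had been seen. Its first version took the BCV from the fit of the real data and recovered fewer of the genes changed 4-fold; the fixed BCV replaced it so that the test comes before the real fit. With 1 dispersion for all genes its prior degrees of freedom are infinite, so it is easier than the real data in this respect. For the genotype comparison (2473 simulated genes), the additive fit recovered 64.7% of genes changed 4-fold and 100% of those changed 16-fold or 64-fold, and called 6 of 2273 unchanged genes. The simulated fold was the same in both growth histories, with no effect of history. In the real data many ratios differ between histories and count as error, so these recoveries do not carry over to the real fit. In the simulated Fe(II) pair (2461 genes), 24.3% of unchanged genes were at least 2-fold apart, against 24.8% in the simulated switched pair (2470 genes). The real pairs had 35.8% and 5.23% of all genes at least 2-fold apart, so the simulated spread is too wide for the switched pair and sets no background for either. Of 26 simulated lists of unchanged genes, 1 fell outside the central 95% of random lists. Those lists were drawn at random from genes simulated independently, so this does not check lists whose genes move together. Genes with near-identical copies (rbcL, rbcS, cysD, tetH, pst and hyp genes) are uncertain, since how shared reads were counted is not given in the sources used here, and reads of overlapping or antisense genes cannot be told apart without a strand setting.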

Results

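The transcriptome of Acidithiobacillus ferrooxidans was measured by RNA sequencing in the wild type and in a deletion mutant of cyc2, the gene of the outer-membrane cytochrome c that takes electrons from Fe(II). Both strains were grown on Fe(II), either from cells already kept on Fe(II) or from cells kept on elemental sulfur and then switched to Fe(II). The 4 combinations had 1 library each, with 7855783 counts for the Fe(II)-grown wild type, 7626859 for the Fe(II)-grown mutant, 9852960 for the switched wild type and 9485952 for the switched mutant. The question was which transcripts differ when cyc2 is missing, in each growth history. There were no replicates, so no ratio below has a replicate check, and the interval given with a ratio covers counting error only.

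The transcript of cyc2 (AFE_RS14445) was present in both wild-type libraries and all but missing from both mutant libraries. It had 38135 counts in the Fe(II)-grown wild type and 4 in the Fe(II)-grown mutant, a log2 ratio of -13.66 (counting interval -15.70 to -12.47). In the switched pair it had 50425 and 0 counts, at least 12164-fold lower in the mutant with the 0 taken as at most 3 counts. The rest of the rus operon, which encodes further carriers of the path from Fe(II) to oxygen, was still abundant in the mutant. Rusticyanin (AFE_RS14415), a periplasmic copper protein, had 33076 and 54867 counts in the Fe(II) pair and 53897 and 49552 in the switched pair, with log2 ratios of 0.12 and 0.35. The gene next to cyc2, a cytochrome c552 (AFE_RS14440), stood at -1.15 on Fe(II) and 0.40 after the switch. The genes of the aa3 oxidase were higher in the switched mutant, 2.82-fold for subunit I (AFE_RS14425) and with log2 ratios of 1.35 for subunit II (AFE_RS14430) and 1.26 for subunit III (AFE_RS14420), but on Fe(II) the log2 ratios were -0.48, -0.56 and -0.91. The remaining gene, AFE_RS14435 with no assigned function, stood at 1.14 and, on Fe(II), at -0.52. On library totals the switched values of rusticyanin and the cytochrome c552 were -0.07 and -0.01, and the Fe(II) values of oxidase subunits I and II and of AFE_RS14435 were 0.16, 0.09 and 0.13, so these directions depend on the scaling.

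**Figure D1:**
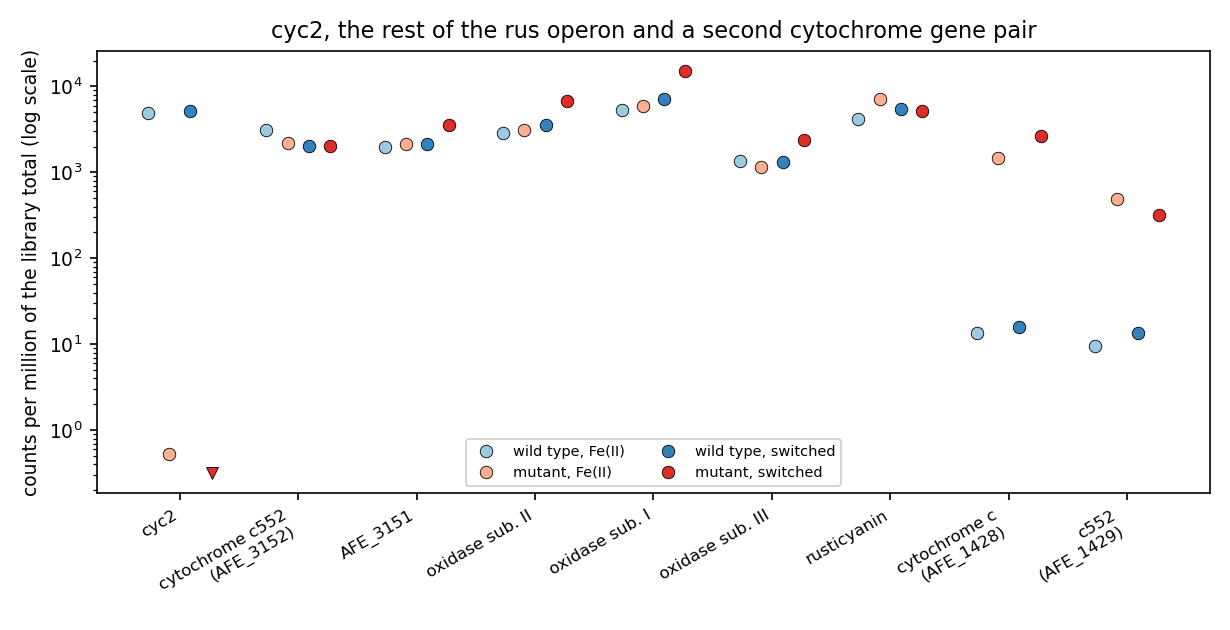
Counts scaled to the library total (log scale) for cyc2, the other 6 measured rus operon genes and the cytochrome genes AFE_1428 (AFE_RS06670) and AFE_1429 (AFE_RS06675), with 1 point per library. The triangle marks a count of 0, drawn at 3 counts; cyc2 has 4 and 0 counts in the mutant libraries, while AFE_RS06670 has 11314 and 25370 there against 105 and 157 in the wild type.

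Compared with the wild type in cells grown on Fe(II), the mutant had far more transcript of a pair of cytochrome genes. The same held for a cluster of genes for the carboxysome and for RuBisCO, the carbon-fixing enzyme, but not for all carbon fixation genes. Transcripts of a small heat-shock protein, the tetrathionate hydrolase gene AFE_RS00135 and hydrogenase were far lower. The cytochrome c gene AFE_RS06670 was 70.4-fold higher (log2 ratio 6.14, counting interval 5.87 to 6.44; 105 and 11314 counts), and its neighbour, the cytochrome c552 gene AFE_RS06675, was 32.3-fold higher (5.01, interval 4.70 to 5.37). A gene annotated as a pilus biogenesis protein (AFE_RS13250, log2 ratio 5.01) and the adjacent AbrB family regulator (AFE_RS13255, 4.70) followed. The other members of the 10 highest were RuBisCO large chain rbcL (AFE_RS07855, 17.9-fold, 1569 and 42737 counts), its small chain (AFE_RS07850, 3.98), carboxysome genes AFE_RS07840 (18.3-fold) and AFE_RS07820 (3.77), AFE_RS07845 of the same cluster (4.01) and an NADH dehydrogenase gene (AFE_RS07710, 4.05). After cyc2, the lowest were the Hsp20 gene AFE_RS09630, whose products bind unfolded proteins (683-fold lower, 34337 and 76 counts), and its neighbour, a hydrolase gene (AFE_RS09625, log2 ratio -7.75). Tetrathionate hydrolase (AFE_RS00135), an enzyme of sulfur oxidation, was 57.1-fold lower, with 9689 and 258 counts. The genes AFE_RS00240 and AFE_RS00200, which carry the symbol tetH, did not share this. They stood at 1.37 and -1.18 on Fe(II), and at 2.29 and 0.36 after the switch. A hydrogenase cluster (AFE_RS15045, AFE_RS15040 and AFE_RS15035) stood at -4.53, -4.52 and -4.48, an ATPase gene (AFE_RS12765) at -4.29, and oxidoreductase genes AFE_RS03815 and AFE_RS03820 at -4.27 and -4.10. Part of these differences lies in the Fe(II)-grown wild type alone. The switched wild type had 40586 counts of rbcL (AFE_RS07855), 258 of tetrathionate hydrolase (AFE_RS00135) and 6845 of AFE_RS15045, where the Fe(II)-grown mutant had 42737, 258 and 2544 and the Fe(II)-grown wild type 1569, 9689 and 38694. AFE_RS06670 and Hsp20 (AFE_RS09630) had 157 and 14437 counts in the switched wild type, far from the 11314 and 76 of the Fe(II)-grown mutant.

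Of 2469 genes in the Fe(II) pair, 442 were at least 2-fold higher and 443 at least 2-fold lower in the mutant (49.9% of them higher). On library totals the same counts were 959 and 223 (81.1% higher). With the switched wild-type library as the control of this mutant library, chosen after the values were seen, they were 93 and 86. Among 481 genes without an assigned function and with a mean of at least 50 counts, 68 were higher and 105 lower, with log2 ratios from -4.30 to 5.09.

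By gene list, transcripts for ribosomal proteins, ATP synthase and NADH dehydrogenase were higher, and those for hydrogenase and the bd quinol oxidase lower, in the Fe(II)-grown mutant than in the Fe(II)-grown wild type. Of 55 genes in the ribosomal protein list, 44 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.12, above all 10000 random lists; rplJ (AFE_RS01500) stood at 3.05 and rpsD (AFE_RS01665) at 3.04. For ATP synthase 8 of 10 genes were higher (median 1.96, 99.99th percentile), for example the beta subunit atpD (AFE_RS14680) at 2.18. For NADH dehydrogenase 12 of 15 were higher (mean log2 ratio 1.22, median above all random lists), with nuoI (AFE_RS12025) at 1.84. Carbon fixation was split, with 5 of 10 genes higher and 4 lower (median 1.11, 99.9th percentile). Hydrogenase genes were lower in 21 of 26 cases and higher in 1 (median -2.00, below all random lists), and 9 of 16 nitrogen fixation genes were lower and 0 higher (median -1.01, below all random lists), among them nifH (AFE_RS07120) at -2.32 from 155 and 47 counts. Oxidative defence had 6 of 15 genes lower and 1 higher (median -0.76, -0.11 on library totals), among them superoxide dismutase (AFE_RS08785) at -2.62. The oxidative defence list lay at the 2.22nd percentile and inside the central 95% with a minimum of 50 counts (2.59) or with stable RNA left out (2.52). Both genes of the bd quinol oxidase, cydB (AFE_RS04465) and AFE_RS04470, were lower at -3.95 and -3.88. Conjugation genes had a median of -0.58 (0.52nd percentile), with 1 of 14 lower, and that median was 0.07 on library totals. On library totals 52 ribosomal protein, 9 ATP synthase and 14 NADH dehydrogenase genes were 2-fold higher, 18 hydrogenase genes 2-fold lower, and only 3 nitrogen fixation genes 2-fold lower (median -0.36). With the switched wild-type library as control, the medians of the Fe(II)-grown mutant were 0.00 for ribosomal proteins, 0.34 for ATP synthase, 0.79 for NADH dehydrogenase, 0.19 for carbon fixation, -0.61 for hydrogenase and -0.41 for nitrogen fixation. Against that control, with all 4 libraries scaled together and a minimum mean of 50 counts, the bd quinol oxidase had a median of -2.02. On that scaling, oxidative defence stood at -0.16 and 8 conjugation genes at -0.08.

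The other lists of the Fe(II) pair lay inside the central 95% of random lists. Their medians were -0.54 for the rus operon, 0.21 for the petI operon of the bc1 complex, -0.12 for the petII operon, 0.36 for the Hdr-like complex, 0.60 for the bo3 quinol oxidase, -0.27 for c-type cytochromes, 0.74 for cytochrome c biogenesis, -0.33 for other sulfur oxidation and 0.65 for sulfate assimilation. They were 0.17 for iron uptake and storage, -0.02 for metal resistance and efflux, -0.16 for chaperones and proteases, -0.42 for phosphate acquisition, 0.47 for type IV pili and motility, -0.08 for exopolysaccharide and cyclic-di-GMP, -0.01 for mobile elements, -0.33 for DNA repair and 0.40 for rRNA- and tRNA-modifying enzymes. The 1 gene of aa3 assembly (AFE_RS14410), too few to rank as a list, stood at 0.61. Every negative median in this paragraph is positive on library totals. Members further from their list included iro (AFE_RS12540) of petII at -2.17, bacterioferritin (AFE_RS07810) at 3.22, mercuric reductase merA (AFE_RS11370) at -2.77 and the RNA chaperone hfq (AFE_RS08715) at -3.46.

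In cells switched from sulfur to Fe(II), the mutant again had far more transcript of the cytochrome pair and far less of Hsp20 than the wild type, and also far more of a dehydrogenase and a porin. AFE_RS06670 was 223-fold higher (log2 ratio 7.80, counting interval 7.58 to 8.04; 157 and 25370 counts) and AFE_RS06675 was 31.5-fold higher (4.98, interval 4.73 to 5.24). The dehydrogenase gene AFE_RS10365 was 60.2-fold higher, with 2850 and 124157 counts, and the adjacent porin gene AFE_RS10360 stood at 5.57. AFE_RS13255 and AFE_RS13250 stood at 4.87 and 4.62, a transketolase gene (AFE_RS07735), whose enzyme serves the Calvin cycle among other paths, at 3.50, tetrathionate hydrolase (AFE_RS00135) at 2.97 from 258 and 1468 counts, the IclR family regulator AFE_RS07740 at 2.96 and the porin gene AFE_RS00140 at 2.87. After cyc2, the lowest genes were again Hsp20 (AFE_RS09630, -5.71, 14437 and 199 counts) and the hydrolase AFE_RS09625 (-4.22). Then came hflX (AFE_RS08720, -2.61), which encodes a ribosome-associated GTPase, and hfq (AFE_RS08715, -2.51). The remaining 5 were a TonB-dependent receptor (AFE_RS13465, -1.53), an AAA ATPase (AFE_RS07005, -1.49), purN (AFE_RS08775, -1.11), a lipase (AFE_RS00550, -1.10) and hda (AFE_RS08795, -1.09).

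Of 2466 genes in the switched pair, 104 were at least 2-fold higher and 25 at least 2-fold lower in the mutant (80.6% of them higher). On library totals these counts were 42 and 125 (25.1% higher), so which side holds more genes depends on the scaling. Among 485 genes without an assigned function and with a mean of at least 50 counts, 28 were higher and 8 lower, with log2 ratios from -1.40 to 4.72.

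By gene list, the switched mutant had more transcript for the rus and petI operons, sulfate assimilation and carbon fixation. The rus operon without cyc2 had 4 of 6 genes at least 2-fold higher (median 1.20, 99.95th percentile). The petI operon had 2 of 3 higher (median 1.22, 98.5th percentile), with cytochrome b (AFE_RS14250) at 1.22. Sulfate assimilation had 6 of 8 higher (median 1.23, above all random lists), among them cysD (AFE_RS13625) at 2.24 and cysN (AFE_RS13630), 5.65-fold higher. Carbon fixation had 3 of 10 higher and 0 lower (median 0.84, 99.99th percentile), with RuBisCO large chain 1 (rbcL, AFE_RS07855) at 1.87. The gene annotated as RuBisCO large chain 2 (AFE_RS13995) had 9919 counts in the switched wild type and 13842 in the switched mutant. Other sulfur oxidation had 2 of 5 higher (median 0.57, 97.8th percentile), and type IV pili and motility had 7 of 37 higher (median 0.17, 99.4th percentile, -0.24 on library totals, and inside the central 95% with a minimum of 50 counts, at 97.2). Hydrogenase genes had a median of 0.43, above all random lists, although 0 of 26 were 2-fold apart (0.02 on library totals). On library totals 1 of 6 rus operon genes (median 0.79), 0 of 3 petI genes (0.81), 3 of 8 sulfate assimilation genes (0.82), 2 of 10 carbon fixation genes (0.43), 2 of 5 other sulfur oxidation genes (0.16) and 3 of 37 pili and motility genes were 2-fold higher. Nitrogen fixation had a median of -0.31 (1.55th percentile, and 4.03 with no minimum count) with 0 of 16 genes 2-fold apart, or 6 lower on library totals.

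The other lists of the switched pair lay inside the central 95% of random lists. Their medians were 0.23 for petII, 0.43 for the Hdr-like complex, -0.02 for the bo3 quinol oxidase, 0.17 for c-type cytochromes, 0.23 for cytochrome c biogenesis, 0.19 for NADH dehydrogenase, 0.23 for ATP synthase, 0.09 for ribosomal proteins and -0.02 for iron uptake and storage. They were 0.05 for metal resistance and efflux, 0.23 for chaperones and proteases, 0.06 for oxidative defence, 0.04 for phosphate acquisition, -0.13 for exopolysaccharide and cyclic-di-GMP, -0.11 for mobile elements, -0.27 for conjugation, -0.08 for DNA repair and -0.07 for rRNA- and tRNA-modifying enzymes. The bd quinol oxidase genes AFE_RS04470 and cydB (AFE_RS04465) stood at 0.47 and 0.34, and aa3 assembly (AFE_RS14410) at 0.52, lists too small to rank. On library totals each positive median of a ranked list in this paragraph other than that of the Hdr-like complex (0.02) is negative.

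**Figure D2:**
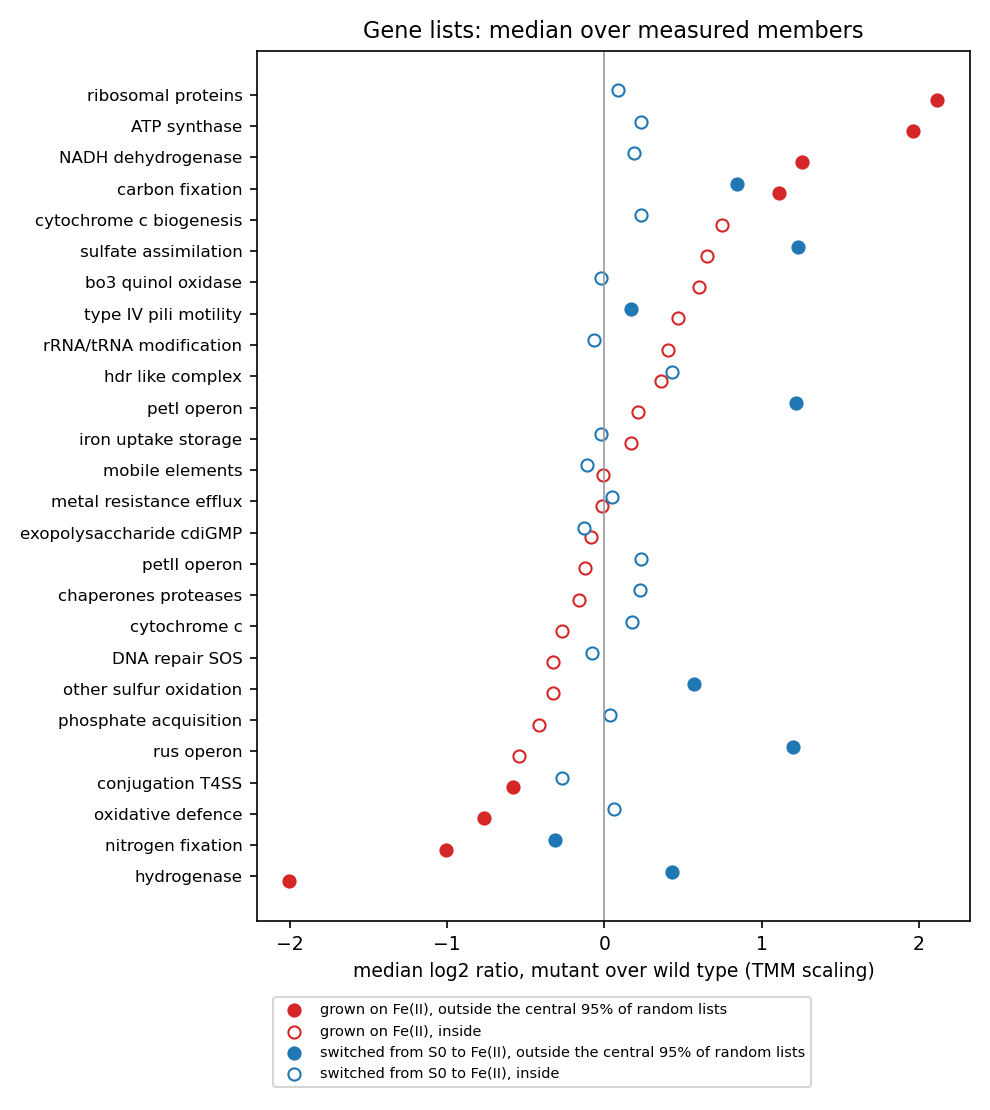
Median log2 ratio of mutant over wild type (TMM scaling) for the 26 lists with at least 3 measured members, grown on Fe(II) (red) and switched from sulfur (blue). Filled points lie outside the central 95% of 10000 random lists matched on mean expression; ribosomal proteins stand at 2.12 and 0.09, and hydrogenase at -2.00 and 0.43.

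Set side by side, the ratios of both growth histories had little in common over most genes and shared a small set of large ones. Over 2458 genes measured in both, Pearson's r was 0.25 and Spearman's rho 0.09; this is a correlation across genes, which are not independent replicates, and r was 0.18 without cyc2. The log2 ratios differed by at least 1 for 906 genes (1523 on library totals), a value without a test. At least 2-fold higher in both were 41 genes, where independent lists would share 18.3, and lower in both were 13, where independent lists would share 4.32. The pairs have separate control libraries. The cytochrome pair, AFE_RS13250 and AFE_RS13255, the RuBisCO genes rbcL (AFE_RS07855) and AFE_RS07850, and cysD and cysN (AFE_RS13625 and AFE_RS13630) were among those higher in both. Those lower in both included cyc2, Hsp20 with its neighbouring hydrolase gene, hfq, hflX and hda. Lower on Fe(II) and higher after the switch were 19 genes, where independent lists would share 18.3. Tetrathionate hydrolase (AFE_RS00135, log2 ratios -5.83 and 2.97) was among them. The reverse held for 2, AFE_RS13465 and, named after its values were seen, the hypothetical gene AFE_RS11145. On Fe(II), AFE_RS13465 stood at 1.003, at the edge of the 2-fold rule. AFE_RS11145 rests on few counts, 4 and 16 on Fe(II) and 40 and 9 after the switch. On library totals these opposite sets held 6 genes, where independent lists would share 3.63, and 30 genes. The 30 come from 951 genes higher on Fe(II) and 122 lower after the switch, and no value for independent lists was computed for them. Higher in both were 28 genes and lower in both 17, where independent lists would share 15.5 and 11.1.

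**Figure D3:**
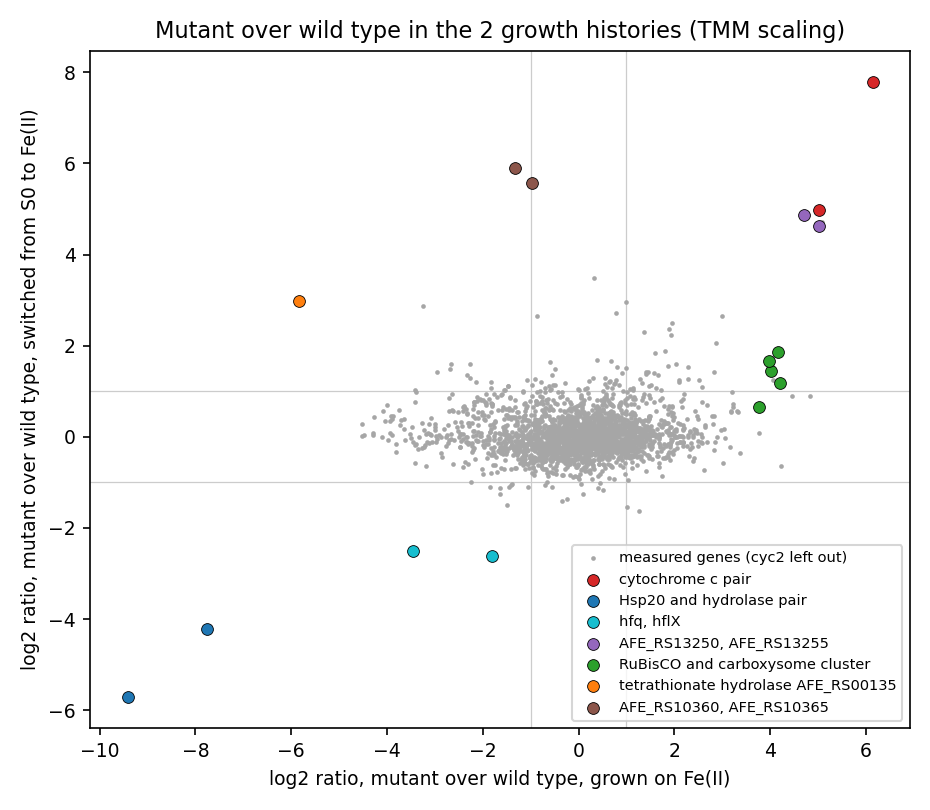
Log2 ratio of mutant over wild type in the Fe(II)-grown pair (horizontal) against the switched pair (vertical), 1 point per gene measured in both, cyc2 left out, with grey lines at a 2-fold difference. The cytochrome pair AFE_RS06670 and AFE_RS06675 lies at 6.14 and 5.01 across and at 7.80 and 4.98 up, and most other genes spread along the horizontal axis.

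With genotype tested over all 4 libraries, the cytochrome pair, cyc2, AFE_RS13250 with AFE_RS13255 and the hypothetical gene AFE_RS13620 had the largest fold changes relative to their errors in edgeR's quasi-likelihood test, and none passed its correction. The edgeR log2 fold change was 5.03 for AFE_RS06675 (SE 0.49, adjusted p = 0.130) and -14.71 for cyc2 (SE 1.52, adjusted p = 0.130), and AFE_RS06670 had an edgeR adjusted p of 0.185 (DESeq2 log2 fold change 6.96, DESeq2 SE 0.65), each in the same direction in both growth histories. edgeR called 0 of 2473 genes, with 72 at an unadjusted p under 0.05. DESeq2 with the same design called 19 (14 higher, 5 lower; 157 unadjusted), and limma on log2(RPKM + 1) called 9 (89 unadjusted), all 9 of them among the 19 of DESeq2. The 9 genes, listed after their values were seen, were cyc2, AFE_RS06670, AFE_RS06675, AFE_RS09625, AFE_RS09630, AFE_RS13250, AFE_RS13255, rbcL (AFE_RS07855) and the hypothetical gene AFE_RS13620, whose log2 ratios were 5.09 and 4.72. Of the fixed lists, edgeR adjusted over the list alone called 3 of 10 c-type cytochromes, 1 of 5 other sulfur oxidation genes, 2 of 8 sulfate assimilation genes and 1 of 37 genes for pili and motility, against 0 over all genes. The 3 c-type cytochromes were the deleted gene cyc2 itself, AFE_RS06670 and AFE_RS06675. Fits without 1 library, and with no history term, were added after the values were seen. Their calls depended strongly on which library was left out. Leaving out the switched wild type sets the Fe(II)-grown wild type alone against both mutant libraries.

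Growth history, tested over both genotypes, gave 0 genes in edgeR (34 at an unadjusted p under 0.05) and 0 in DESeq2 (63 unadjusted). limma called 1 (27 unadjusted), the dehydrogenase gene AFE_RS10365, named after its values were seen, higher after the switch at a log2 fold change of 3.78 (limma adjusted p = 0.00695) and carried by the switched mutant with 124157 counts. On library totals, log2 ratios of switched over Fe(II)-grown cells shift by 0.42 in the wild type and -0.68 in the mutant. Several groups differed by history in other directions or sizes in the mutant than in the wild type. In the wild type, ribosomal protein genes were higher after the switch (median 2.04, 44 of 55 at least 2-fold) and hydrogenase genes lower (median -1.50, 18 of 26). In the mutant, ribosomal protein genes had a median of 0.07 (-0.62 on library totals) with 0 of 55 genes 2-fold apart, hydrogenase genes were higher (median 1.05, or 0.37 on library totals; 13 of 26), and rus operon genes were higher (median 1.58, or 0.89; 4 of 6). These values have no test of the difference. For growth history too, calls from fits without 1 library, chosen after the values were seen, depended on the library left out. Leaving out the Fe(II)-grown mutant sets the Fe(II)-grown wild type alone against both switched libraries.

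In the authors' deposited tables, 2053 genes of the Fe(II) pair (81.7%) and 1829 of the switched pair (72.7%) had an FDR of at most 0.001. A test on the reads of 2 libraries compares those libraries and not the conditions, since it holds no spread between cultures. The median of the authors' log2 ratios was 0.69 in the Fe(II) table and -0.42 in the switched table.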

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

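All tests of explanations below were chosen after the results were seen. The differences between growth histories in the next paragraph were not tested, since each rests on 1 library per group.

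Several results went in opposite directions in the growth histories, though the 19 genes lower on Fe(II) and higher after the switch are about what independent lists would share (18.3). Tetrathionate hydrolase (AFE_RS00135) stood at -5.83 on Fe(II) and 2.97 after the switch, a difference of -8.81 in log2 ratio, with 9689, 258, 258 and 1468 counts in the Fe(II)-grown wild type and mutant and the switched wild type and mutant. Its neighbour, the porin gene AFE_RS00140, differed by -6.11 (-3.24 and 2.87). The dehydrogenase gene AFE_RS10365 differed by -7.23 (-1.32 and 5.91). The TonB-dependent receptor AFE_RS13465 differed by 2.53, with 98 and 300 counts on Fe(II) and 576 and 144 after the switch. The hydrogenase list had medians of -2.00 and 0.43, a difference of -2.43, and lay beyond random lists on opposite sides, although the second median is 0.02 on library totals.

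The mutant and wild type differed more on Fe(II) than after the switch. Lower depth does not account for it, since the libraries were close in depth (7626859 to 9852960 counts). Thinning them to 1 total could therefore change little. The spread of log2 ratios on Fe(II) was 2.23 times that after the switch, both before and after thinning. This spread was taken over genes with a mean of at least 50 counts, cyc2 left out. The 881 genes at least 2-fold apart on Fe(II) (median size 1.56) had a median of 0.0302 in that direction after the switch (quartiles -0.24 and 0.28), which describes the same pattern on genes chosen by it and excludes no explanation. The values needed for a wild-type Fe(II) library that stands apart on its own are there: the smallest spread over pairs with that library was 1.74 times the largest over pairs without it (SD 1.06 and 0.61). Growth stage at harvest, the culture itself, library preparation and a response to cyc2 loss that needs the Fe(II) history may each lie behind that. None of these was tested. A swap of the wild-type libraries would not make a library stand apart. Such a swap would change only which pair holds that library, and it was not tested.

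The cytochrome pair AFE_RS06670 and AFE_RS06675 was far higher in both mutant libraries. With cyc2 deleted in the mutant, reads of cyc2 transcripts assigned to the pair could raise it only in the wild type. They could not give this pattern, so the design settles that explanation and the test adds nothing to it. In the wild type the pair had at most 0.00577 times the count of cyc2 (291 and 50425 counts), while its lowest count in the mutant was 0.395 times that of cyc2 in the wild type. A longer duplicated stretch is argued against by the 4 flanking genes, whose highest log2 ratio was 0.36 with TMM scaling. On library totals the Fe(II) ratios are 0.65 higher, which brings the flanking gene AFE_RS06665 (0.34 on Fe(II) with TMM) close to 2-fold. In the switched pair that gene stood at -0.39 with TMM, and library totals lower it further. Under the other scalings, added count and minimums the pair stayed higher, with 4.57 the lowest of 28 values. Library totals shift log2 ratios by at most 0.65, and a minimum does not change a ratio. This check could therefore hardly come out otherwise. A response of these genes to the loss of cyc2 may explain the pattern, as a hypothesis found and examined on the same libraries; a second change in the mutant strain, such as a promoter mutation, was not tested.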

How the results depend on the processing

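The switched wild type as control, the fits without 1 library and the correlation without cyc2 were chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because each group had 1 library and so no replicate number to pair on; the additive fit does set strains against each other within each growth history. Library totals, and the authors' log2 ratios, which are scaled that way, moved the counts of genes at least 2-fold apart: on Fe(II) to 959 and 960 higher and 223 and 225 lower (442 and 443 with TMM), after the switch to 42 and 42 higher and 125 and 127 lower (104 and 25). With the switched wild type as control, the Fe(II)-grown mutant had 93 higher and 86 lower genes, and the medians of the 6 lists compared lay nearer 0. The other alternatives kept these counts within 1.5 times. Genotype calls were 0 with edgeR and without a filter, but 8 on library totals, 19 with DESeq2, 3 with DESeq2 size factors in edgeR (cyc2, AFE_RS06675 and AFE_RS13620), 9 with limma and 6 without a history term. Leaving out each library in turn, with no other-factor term, gave 7 to 644, the highest without the switched wild type; the lone library of a strain is then assumed to vary like the others. Growth history calls were 0, except 1 with limma, and 0 to 439 without each library, the highest without the Fe(II)-grown mutant. Each of these extremes leaves the Fe(II)-grown wild type alone against a pair of libraries; the cause was not tested further. Genes whose log2 ratios differed by at least 1 between histories numbered 906, and 1523 on library totals; r fell from 0.25 to 0.18 without cyc2. A scaling shifts all genes of a pair alike, so it cannot move r. Under another scaling a list's percentile moved only because the random lists were drawn again, as from 1.55 to 1.81 for nitrogen fixation after the switch. The move of oxidative defence on Fe(II) from 2.22 to 2.52 with stable RNA left out is about as large as such a redraw. Lists outside the central 95% numbered 8 per comparison and 7 to 8 over the alternatives: oxidative defence on Fe(II) moved inside with a minimum of 50 or stable RNA left out, and after the switch nitrogen fixation did with no minimum and pili with a minimum of 50. Of 129 named values at least 2-fold apart, 101 stayed so on library totals and 129 under the settings that kept TMM or used DESeq2 size factors. Library totals shift log2 ratios by at most 0.65, so none of these values, each at least 1 in size, could change sign there.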

Other observations

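All observations here were made after the values were seen and have no test across replicates. Neighbouring genes moved together in several places. On Fe(II), genes around RuBisCO and the carboxysome were higher in the mutant, from AFE_RS07820 (log2 ratio 3.77) to rbcL (AFE_RS07855, 4.16), and the same genes were higher in the switched than in the Fe(II)-grown wild type (3.67 and 3.95, libraries scaled together). A run of genes with glycosyl transferases and UDP-glucose dehydrogenase (AFE_RS02885, AFE_RS02890, AFE_RS02895 and AFE_RS02905) was lower in the Fe(II)-grown mutant at -2.96, -2.32, -2.28 and -2.15 and higher in the switched mutant at 1.42, 1.37, 1.30 and 1.21. The genes gfa (AFE_RS03290, aldehyde-activating protein), AFE_RS03295 (alcohol dehydrogenase) and fghA (AFE_RS03300, S-formylglutathione hydrolase) did likewise at -2.27, -2.67 and -1.53 against 1.60, 1.59 and 1.03. Glycolate oxidase genes glcF (AFE_RS07715) and glcE (AFE_RS07720) were higher in both histories, at 1.66 and 2.04 on Fe(II) and 1.35 and 1.59 after the switch, and so was a phospholipase C gene (AFE_RS10435) at 2.99 and 2.65.

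Between growth histories, the bd quinol oxidase differed in opposite directions in the strains, with no test of the difference. In the mutant, the bd quinol oxidase genes were higher after the switch (median 2.43, or 1.75 on library totals), and in the wild type lower (-1.93, or -1.51). Sulfate assimilation genes were higher in the Fe(II)-grown mutant than in the switched wild type (median 1.03, 4 of 8 at least 2-fold), a comparison that crosses strain and history. The adjacent genes AFE_RS10365 and AFE_RS10360 had 124157 and 23954 counts in the switched mutant against 851 and 285 in the Fe(II)-grown mutant.

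Over the 6 pairs of libraries, Spearman's rho across 2345 genes was 0.79, 0.86 and 0.84 for pairs with the Fe(II)-grown wild type and 0.95, 0.96 and 0.96 for pairs without it. Genes at least 2-fold apart numbered 837, 664 and 769 in the first set and 159, 204 and 116 in the second.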
